A study of Arabidopsis thaliana with 12 samples.

How the data were processed

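The series holds hybridization values of Arabidopsis thaliana RNA on an array of 3439 probes in 12 samples. Per the labels, all plants were wild type of the Landsberg ecotype. The 6 samples of the dark group came from plants kept in the dark for 12 h, and the 6 samples of the light group from plants given 30 min of light after 12 h of darkness. Samples were grouped and numbered 1 to 6 from their titles, and every column was used.

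The deposited values are intensities on a linear scale from 0 to 100, with no blank and no negative value. The scanner, the background correction, the scaling and the number of plants or membranes behind each sample are not given in the sources used here, so the unit to which the intensities are relative stays unknown. The column medians were 0.443, 0.454, 0.491, 0.491, 0.466 and 0.458 in dark samples 1 to 6, and 0.682, 0.680, 0.687, 0.682, 0.671 and 0.666 in light samples 1 to 6. Between 108 and 153 probes per column were listed at 0. In each dark column 2 probes stood at 100, the highest value listed, to within rounding of the last digit. No measure of depth or background accompanies the values, and the number of samples limits the precision.

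Because the log2 column medians differed by more than 0.1, the rule fixed before the data were examined called for quantile normalization of the linear values. After it, values below the 5th percentile of the positive values of a column were raised to that floor, and log2 was taken. Light was compared with dark by lmFit and eBayes of limma 3.58.1 in R 4.3.3, with 6 samples per group, no block and no trend. Probes with a Benjamini-Hochberg adjusted p under 0.05 were called. All adjusted p-values of genes are from limma and two-sided. Array medians of the deposited values were compared by an exact two-sided permutation test over all 924 assignments of the 12 samples. Gene lists were tested with camera of limma at a preset correlation of 0.01, and again with an estimated correlation.

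The platform annotation named 1 gene for 692 probes and several genes for 870. The remaining 1877 probes are unnamed here. Of the 692 probes that name 1 gene, 690 were matched by gene identifier to a table of the TAIR10.1 assembly, which supplied current symbols and no coordinates. No gene was named from a probe with several genes, and 1 gene had more than 1 probe.

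The genes named were fixed by a rule before the data were examined. It took the 10 largest rises and the 10 largest falls among called probes that name 1 gene and lie above the 25th percentile of mean level. It also took, for each of 24 gene lists with at least 4 measured members, up to 4 called members, and 20 marker genes of light and dark responses where measured. None of the 20 markers was measured by a probe that names 1 gene. Of the 439 list members, written from general knowledge, 17 were measured in this way. For the plastid ribosomal proteins and the peroxiredoxin the TAIR10.1 table gives no descriptive name, so their place in a list rests on that knowledge. They fell in 8 lists, 16 lists had no measured member, and only the list of plastid ribosomal proteins reached 4 members. The measured members of the other 7 lists stand outside the rule and were chosen after their values were seen.

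The replicate numbers are shared by both groups, so it was checked whether they pair the samples. Across probes, the deviations from the group means of equally numbered dark and light samples correlated at 0.41 to 0.65, and every dark sample correlated best with the light sample of its own number. By the criterion of a correlation over 0.1 in every pair, the numbers pair the samples, although no label says what a number marks. Consecutive numbers (1 and 2, 3 and 4, 5 and 6) also resembled each other within a group, at 0.42 to 0.60 in the dark and 0.36 to 0.47 in light. Within a group, numbers of different pairs correlated below 0. Deviations from a group mean sum to 0 for each probe, so some negative correlation is built in. Only the contrast with the consecutive numbers is informative. Nothing in the labels says that the 6 samples of a group came from separate plants. The p-values therefore measure the spread between samples that may partly be repeat readings.

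The fits were tested on simulated data with the variance structure of the real samples, including the pairs of consecutive numbers, with 200 of 3439 probes changed and 5 draws of the light against dark comparison. The comparison of 6 against 6 recovered 54.3% of 1.5-fold, 80.6% of 2-fold and 98.5% of 4-fold changes, but 27.1% of its calls were false. With the replicate number as a block 40.5% of calls were false. With each pair of consecutive numbers averaged first, giving 3 against 3, 2.5% of calls were false, and 11.3% of 1.5-fold, 41.5% of 2-fold and 89.4% of 4-fold changes were recovered. With averaged pairs and the pair as a block 4.2% of calls were false, and 3.3% of 1.5-fold, 49.3% of 2-fold and 90.6% of 4-fold changes were recovered. The design of 6 against 6 had been fixed before the data were examined and was kept, and the result with averaged pairs is given beside it.

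Alternatives fixed before the data were examined were the deposited values without further scaling, centring on array medians, cyclic loess, floors at the 1st and 20th percentiles, values at 0 set to missing, leaving out probes below the 25th percentile or below the median of mean level, eBayes with trend and robust, the replicate block, averaged pairs, array weights and leaving out each sample. Those chosen after seeing the data were averaged pairs with the pair as a block, the pair within a group as a random block, leaving out each pair of numbers, leaving out probes mostly at the floor, list membership that includes probes naming several genes of the list, a joined photosynthesis list under each of the 4 scalings, and medians without the 20 brightest probes.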

Results

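Transcript levels were measured on an array of 3439 probes in 6 samples of dark-adapted Landsberg wild-type Arabidopsis plants and in 6 samples of plants moved into light for 30 min after 12 h of darkness. The comparison asks which transcripts differ after this short exposure to light. No group was kept in the dark for the added 30 min, so light and elapsed time cannot be told apart as sources of a difference. The deposited intensities summed to between 3247 and 3321 per dark sample and to between 3532 and 3666 per light sample.

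**Figure D1:**
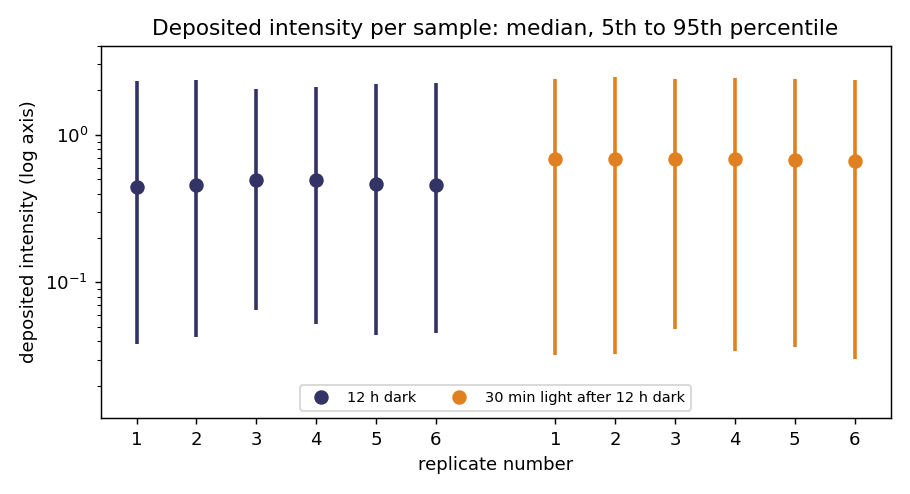
Deposited intensity (log axis) of each sample by replicate number, with the median as a point and the 5th to 95th percentile as a line. The 6 light medians lie between 0.666 and 0.687 and the 6 dark medians between 0.443 and 0.491.

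The median intensity of an array was higher in light, at 0.678 ± 0.00794 (SD, n = 6), than in the dark, at 0.467 ± 0.0202 (SD, n = 6). On the log2 scale the difference was 0.54, or 1.45-fold (exact two-sided permutation test, p = 0.00216, the smallest that 924 assignments can give). It was 0.60, 0.48 and 0.53 for samples 1 and 2, 3 and 4, and 5 and 6. The permutation p takes the 12 samples as independent, although consecutive numbers resemble each other. With the 3 pairs as units, 10 splits are too few for a p under 0.05. The 20 brightest probes held 22.6% ± 0.634 (SD, n = 6) of the total intensity in the dark and 16.7% ± 0.467 (SD, n = 6) in light. The scaling of the deposited values is unknown, and differences of genes below are relative to a common distribution set by quantile normalization.

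Among genes measured by their own probe and above the 25th percentile of mean level, the strongest rise was that of AT1G51350, whose deposited intensity was 0.732 ± 0.138 in the dark and 6.77 ± 0.972 in light (SD, n = 6 each). Its log2 difference after normalization was 3.21 ± 0.14 (SE), or 9.23-fold (limma adjusted p = 1.64e-09). Folds and log2 differences are of normalized values throughout and can differ from the ratio of the deposited intensities given beside them. AT1G35510 rose 8.07-fold after normalization, with deposited intensities from 1.88 ± 0.505 to 13.3 ± 0.666 (SD, n = 6 each, limma adjusted p = 1.90e-08). AT5G58330, the NADP-dependent malate dehydrogenase of the chloroplast, which exports reducing power as malate, rose 7.50-fold after normalization, with deposited intensities from 0.884 ± 0.394 to 6.02 ± 0.499 (SD, n = 6 each, limma adjusted p = 1.63e-06). AT5G55580, which encodes mTERF9, a member of the organellar transcription termination factor family, rose 5.94-fold after normalization, with deposited intensities from 0.426 ± 0.0668 to 3.13 ± 0.382 (SD, n = 6 each, limma adjusted p = 2.16e-09). The other 6 of the 10 largest rises were AT1G24040, AT4G09040, AT3G25680, AT5G46560, AT3G52070 and AT4G32060, with log2 differences of 2.80, 2.26, 2.23, 2.22, 2.21 and 2.21. For AT3G25680, 2 of the 6 dark values were at the floor, so its difference depends on the floor.

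Among the same genes the strongest fall was that of AT1G62250, from 12.5 ± 1.65 in the dark to 1.55 ± 0.0542 in light (SD, n = 6 each), a log2 difference of -2.96 ± 0.08 (SE, limma adjusted p = 4.21e-11). CUTA (AT2G33740), related to bacterial copper tolerance proteins, fell from 10.9 ± 1.17 to 1.65 ± 0.123 (SD, n = 6 each), a log2 difference of -2.63 (limma adjusted p = 4.78e-10). LpxA (AT4G29540), which resembles the bacterial acyltransferase that starts lipid A synthesis, fell from 2.59 ± 0.370 to 0.726 ± 0.0377 (SD, n = 6 each), a log2 difference of -2.11 (limma adjusted p = 2.56e-09). CYN (AT3G23490), the cyanase that breaks down cyanate, fell from 2.21 ± 0.515 to 0.803 ± 0.111 (SD, n = 6 each), a log2 difference of -1.69 (limma adjusted p = 3.85e-07). The other 6 of the 10 largest falls were AT3G09080, AT1G03810, AT4G30740, AT1G21660, AT4G31470 and AT1G15140, with log2 differences of -2.51, -2.36, -1.88, -1.85, -1.82 and -1.65.

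**Figure D2:**
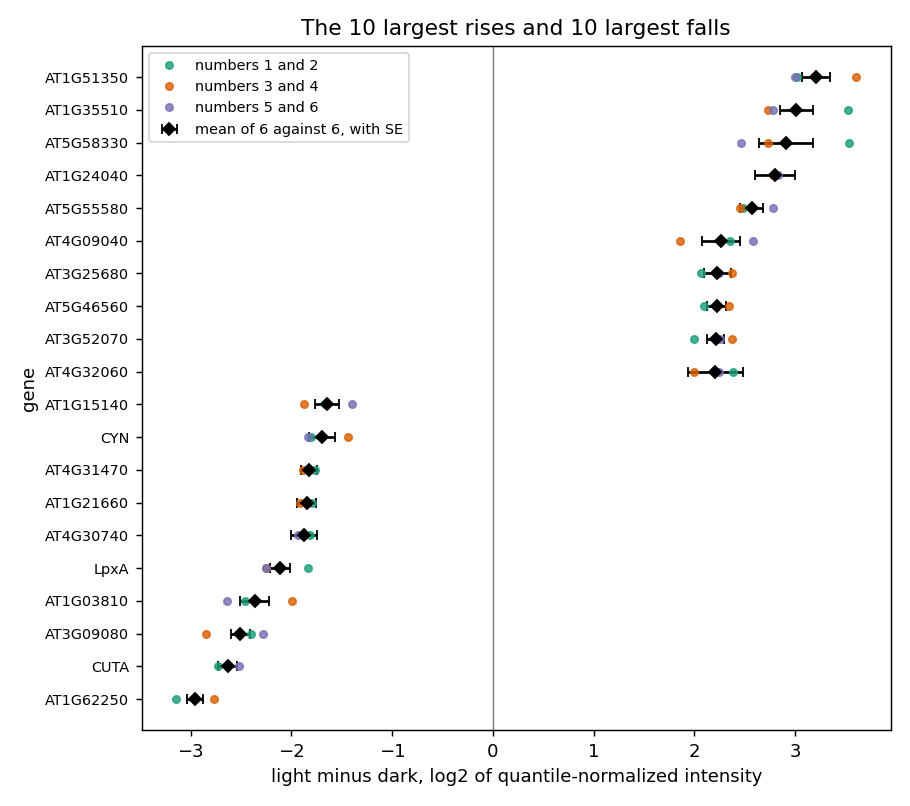
Light minus dark difference (log2 of quantile-normalized intensity) of the 10 largest rises and 10 largest falls, with the mean of 6 against 6 samples and its SE as a diamond, and the difference of each pair of consecutive replicate numbers as a point. All 3 pairs lie on the side of the mean for each of the 20 genes, from AT1G62250 at -2.96 to AT1G51350 at 3.21.

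All 20 genes changed in the same direction in the 3 pairs of consecutive numbers. With each pair averaged, 3 against 3, all 20 were still called, with limma adjusted p-values of at most 0.00697 for the rises and 0.00162 for the falls. All 20 were also called in the same direction on the values as deposited. The 20 were picked for large differences in these same samples, so such agreement is no independent support.

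Over all probes, 811 were higher and 996 lower in light, 1807 of 3439 (limma adjusted p under 0.05). Of these, 317 rose and 274 fell by at least 2-fold, and 589 of these 591 had the same direction in all 3 pairs. The pairs are parts of the samples that gave the calls, so this is no independent support. Among the 692 probes that name 1 gene, 169 were higher and 169 lower. With the pairs averaged, 520 probes were higher and 679 lower, 1199 in all, and 1192 of them were among the 1807 with the same direction. Simulated data had 200 changed probes and samples paired as here. In them 27.1% of the calls of 6 against 6 were false, against 2.5% with the pairs averaged. A false share depends on how many probes truly change, so neither figure carries over to the 1807 or the 1199 calls. The 1807 calls may still include more false ones than the threshold implies.

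The balance of rises and falls depended on the scaling, so it is not settled whether more transcripts rose or fell. On the values as deposited, 1715 probes were higher and 479 lower, where the median difference of all probes was 0.44 on the log2 scale. That is also the difference of the column floors, and 153 of the higher probes were at the floor in all 12 samples. Centring each array on its median gave 686 higher and 1117 lower, and cyclic loess 852 and 944. A core of 674 higher and 469 lower probes was called in the same direction under all 4 scalings, and 493 and 463 of them also with the pairs averaged.

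Of the 17 measured members of the gene lists fixed before the data were examined, 5 rose, 8 fell and 4 were not called. This balance depended on the scaling, as 6 were called higher and 5 lower on the values as deposited, leaving out AT5G65220, which was at the floor in all 12 samples. With the pairs averaged, 9 of the 17 were called. Plastid ribosomal proteins, which belong to the chloroplast translation machinery, formed the only list with enough members to test. Of its 6 measured members, AT4G01310 (large subunit protein 5) rose, with a log2 difference of 0.98 ± 0.13 (SE, limma adjusted p = 4.64e-05). The falls were those of AT1G64510 at -1.04 ± 0.13, AT3G54210 at -1.02 ± 0.09 and AT3G13120 at -0.86 ± 0.13 (log2 difference ± SE), the last of which was not called on the deposited values. For AT1G64510, 1 light value was at the floor, so the size of its fall depends on the floor. AT1G29070 had a difference of 0.23 ± 0.22 (log2 ± SE, limma adjusted p = 0.405) but was called as deposited, at 0.65 (limma adjusted p = 0.00739). AT5G65220 was at the floor in all 12 samples, so it has no measured difference. Adjusted over the list alone, again 1 rose and 3 fell. As deposited, AT4G01310 and AT1G29070 were called higher and AT1G64510 and AT3G54210 lower. No shift of the list against the other genes was detected (camera adjusted p = 0.338, and adjusted p = 0.349 with an estimated correlation). Without probes at the floor in most samples, which leaves 5 members, the camera adjusted p was 0.207 (adjusted p = 0.289 with an estimated correlation).

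Among genes of the photosynthetic apparatus, LHB1B2 (AT2G34420), which encodes an antenna protein of photosystem II, fell from 17.5 ± 2.98 to 5.83 ± 0.597 (SD, n = 6 each), a log2 difference of -1.26 ± 0.14 (SE, limma adjusted p = 8.52e-06). Near-identical copies of this antenna gene exist and may bind the same probe, so the value is uncertain as to the copy. PSAN (AT5G64040), a subunit of photosystem I, had a log2 difference of -0.99 ± 0.15 (SE, limma adjusted p = 0.000131), and PRK (AT1G32060), the phosphoribulokinase of the Calvin cycle, one of -1.12 ± 0.17 (SE, limma adjusted p = 9.94e-05). These 3 falls were called under all 4 scalings and with the pairs averaged. PSBW (AT2G30570), a small subunit of photosystem II, had a log2 difference of 0.50 ± 0.09 (SE, limma adjusted p = 0.000379) and was called higher with the pairs averaged and with loess, at 0.84, but stood at 0.08 as deposited and at -0.46 with centred arrays, where it was called lower (limma adjusted p = 0.0106). PSBY and SBPASE, of photosystem II and the Calvin cycle, were not called, at -0.06 and -0.05, but SBPASE was called higher as deposited, at 0.46, and PSBY lower with centred arrays, at -0.38 (limma adjusted p = 0.0262). With centred arrays 5 of the 6 photosynthesis genes were called lower and 0 higher, against 3 lower and 1 higher as deposited. Centring lowered every light minus dark difference by the same 0.54 from its value as deposited, which moves such counts towards falls. Joined into 1 list of 6 genes after the data were seen, the photosynthesis genes gave a camera p of 0.154 after quantile normalization (0.175 with an estimated correlation). The camera p was 0.202 after loess, 0.0113 with centred arrays and 0.00599 as deposited (0.0180 with an estimated correlation). Each run tested this list alone, so these p-values carry no correction for the 4 scalings tried.

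In the tetrapyrrole pathway, which makes chlorophyll and haem, HEMA3 and AT1G74470, the geranylgeranyl reductase, had log2 differences of 0.31 and 0.31, and CHLM, the magnesium protoporphyrin methyltransferase, of -0.48. The limma adjusted p-values were 0.0444, 0.0262 and 0.0448, and none of the 3 was called with the pairs averaged. CHLM stood at -0.03 as deposited and was not called there (limma adjusted p = 0.905). It was called lower with centred arrays, at -0.57 (limma adjusted p = 0.0212). With centred arrays HEMA3 stood at 0.16 (limma adjusted p = 0.336) and AT1G74470 at -0.03 (limma adjusted p = 0.850), neither called. As deposited both were called higher, at 0.70 (limma adjusted p = 0.000238) and 0.51 (limma adjusted p = 0.00238). All 3 were called with loess, in the same direction as after quantile normalization. The plastid peroxiredoxin AT3G52960 rose 3.02-fold after normalization, with deposited intensities from 0.299 ± 0.0870 to 1.18 ± 0.142 (SD, n = 6 each, limma adjusted p = 2.58e-05), and was called under all 4 scalings and with the pairs averaged. FATB, a thioesterase that releases saturated fatty acids in the plastid, had a log2 difference of -0.49 (limma adjusted p = 0.0220) and was called neither with the pairs averaged (adjusted p = 0.0622) nor as deposited. For FATB, 1 light value was at the floor.

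**Figure D3:**
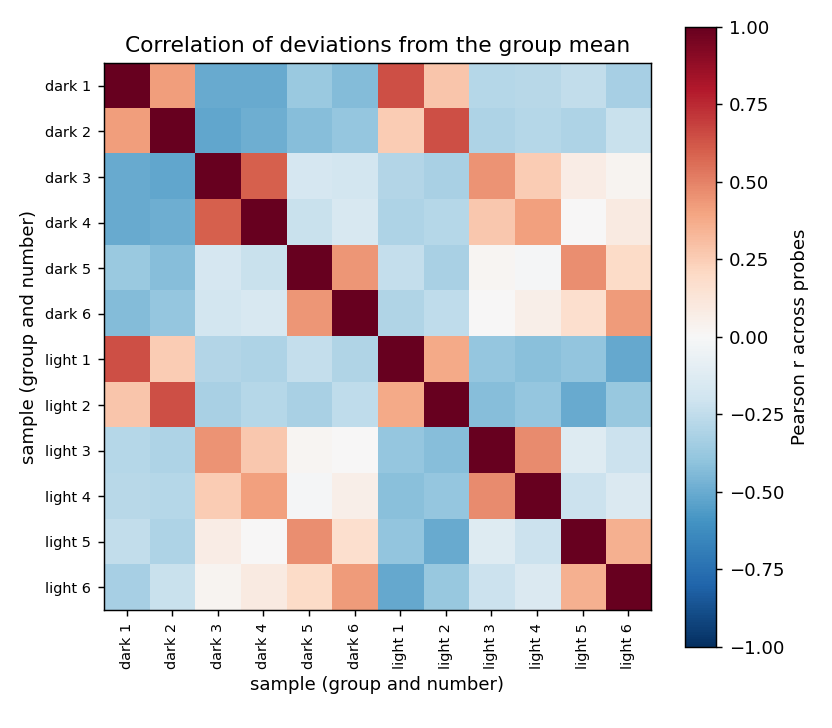
Pearson correlation across probes, from -1 to 1 as colour, between the deviations of the 12 samples from their group means, with samples by group and number on both axes. Equal numbers in dark and light correlate at 0.41 to 0.65, and consecutive numbers within a group at 0.36 to 0.60.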

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

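All tests in this part were chosen or written down only after the results were seen. Among 112 groups of 6 values examined, 5 had a sample far from the others, and chance alone gives about 1 in 20.

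LHB1B2 stood at a normalized log2 value of 4.45 in dark sample 6, against 3.77 to 4.02 in the other 5 dark samples. AT3G25680 stood at -0.657 in light sample 6, against -0.322 to -0.147 in the others. AT3G13120 stood at -2.20 in light sample 5, against -1.84 to -1.70. AT5G65220 stood at -2.96 in dark sample 2, against -2.86 to -2.82, all of them floor values. Dark sample 2 listed 108 probes at 0, against 123 to 131 in the other dark samples.

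The first pattern is the higher median of the light arrays, 0.54 on the log2 scale. The 20 brightest probes cannot account for all of it: without them and at equal totals the difference was smaller but still 0.286. A constant background added to every light value would raise the dimmest probes as much as the median. The 5th percentile differed by -0.0120, but it lies close to the probes listed at 0. Among positive values it rose from 0.123 in the dark to 0.167 in light, less than the median did, from 0.467 to 0.678. A background could thus not be the whole cause, but a smaller one is not excluded. A single scaling factor per column would move all percentiles alike, whereas the light over dark log2 ratio ranged over 0.419 between the 25th and 95th percentiles, from 0.54 at the median to 0.12 at the 95th. A scaling that acts on dim and bright probes differently, and a real shift from a few abundant transcripts to many weaker ones in light, both stay open and may act together.

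The second pattern is that 1807 of 3439 probes were called. Of 100 splits of the 12 samples into 6 and 6, the real one included, 1 gave as many probes, and the highest other split gave 3, which excludes chance only if the 12 samples are independent, although consecutive numbers resemble each other. The same held for the 811 higher and the 996 lower probes, with 3 as the highest other in either direction, and among the 32 splits that part all 6 equal numbers the highest other gave 0. Counting the 2 numbers of a pair as separate samples cannot be the whole cause, as 66.0% of the calls were also made with the pairs averaged. It may add false calls. Averaging cannot tell whether the 3 pairs are themselves repeat readings of the same plants, so that stays open. For the 1199 probes of that comparison, the 10 splits of 3 against 3 are too few for a share under 0.05, and the highest other gave 0.

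The third pattern is that equally numbered dark and light samples deviate together. If a pair of consecutive numbers marked only a shared experiment, a sample would resemble both numbers of its pair in the other group alike, but its own number correlated better by at least 0.145. If equal numbers marked only a shared spot or membrane, the other number of the pair would be no closer than the rest, but the lowest such correlation exceeded the highest with other pairs by 0.0808. A candidate explanation is that both hold, with 3 experiments read on a pair of spots or membranes each, and it was not tested on other data. No biological explanation was tested.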

How the results depend on the processing

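The 20 genes with the largest changes kept direction and call under every alternative run, except that 3 of them were not tested once the probes below the median level were left out. Genes picked for large changes in these same samples were likely to do so. No gene list with at least 4 members was called under any alternative fixed beforehand that left a list to test. Without the probes below the 25th percentile, or below the median, no list kept 4 members. The median array signal stayed higher in light under all alternatives, at 0.29 to 0.55 on the log2 scale.

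As deposited, 1715 probes were higher and 479 lower, and all 153 probes at the floor in every sample were called there, against 0 after quantile normalization; those calls come from the floors of the columns. Testing only probes above the median level gave 1077 calls (511 higher, 566 lower), with fewer probes tested. Averaged pairs gave 1199 calls, 520 of them higher, with fewer samples, and 1583 with the pair as a block. With the pair within a group as a random block the count was 1376. With the replicate number as a replicate block the count was 2069 (966 higher, 1103 lower); it added CRR21 and NdhN to the calls and changed no other call of a named gene, and with the pairs averaged neither was called (limma adjusted p = 0.208 and 0.805). Leaving out single samples gave 1688 to 1818 calls. The joined photosynthesis list, added after seeing the data, was called as deposited and with centred arrays, so 1 list passed in each of them, and not with cyclic loess. Centring moves every difference by the same amount, and camera compares a list with the other genes. These 2 passes are therefore not separate support. Among genes called under either setting, the values that changed sign were SBPASE 0.46, NTRC 0.35 and SRX 0.11 as deposited, AT1G74470 -0.0299 and PSBW -0.46 with centred arrays, and FATB 0.0122 with a floor at the 20th percentile; the cause was not tested. Another 5 genes, called in neither, changed sign as deposited, 2 with centred arrays and 1 with cyclic loess.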

Other observations

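The genes and tests in this part were chosen after the values were seen. The chloroplast NDH complex carries electrons around photosystem I. Of the 5 probes for its subunits and assembly or editing factors, NdhS rose from 4.50 ± 2.54 to 10.8 ± 1.07 (SD, n = 6 each), a log2 difference of 1.68 ± 0.32 (SE, limma adjusted p = 0.000704). CRR41 rose by a log2 difference of 1.36 ± 0.14 (SE, limma adjusted p = 3.43e-06). Both were called under all 4 scalings and with the pairs averaged. CRR21, NdhN and PIFI were not called, at 0.52, 0.20 and -0.24, but as deposited CRR21 was called, at 0.89 (limma adjusted p = 0.00670), and PIFI stood at 0.20. PIFI was at the floor in 2 dark and 3 light samples, so its value and its part in the mean depend on the floor. The mean of the 5 genes, 0.70, was not far enough from that of random sets of genes to tell a joint rise from chance (permutation p = 0.0639 with 100000 draws, adjusted p = 0.0897 over 2 gene families). It depended on the scaling, at 0.98 as deposited, 0.44 with centred arrays and 0.80 with loess.

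Of 4 measured endoglucanases of the GH9B family, enzymes that act on cellulose in the cell wall, GH9B8, GH9B11 and GH9B16 had log2 differences of -1.12, -0.70 and -0.51 and were called, and GH9B12 stood at -0.06. For GH9B8, 1 light value was at the floor, so the size of its fall depends on the floor. With the pairs averaged GH9B11 was not called (limma adjusted p = 0.0516). As deposited GH9B8 was the only one called, and GH9B12 stood at 0.40. The mean of the 4, -0.60, did not differ from random sets beyond chance (permutation p = 0.0897 with 100000 draws), so a joint fall stays open. The mean depended on the scaling, at -0.14 as deposited, -0.68 with centred arrays and -0.57 with loess.

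Another 6 chloroplast genes were looked up by name. Cpn60beta4, a chaperonin subunit, rose by a log2 difference of 1.70 ± 0.12 (SE, limma adjusted p = 2.40e-07), a size that depends on the floor, at which 2 of its 6 dark values stood, and its relative Cpn60beta3 was not called, at -0.18, or 0.36 as deposited; the difference between them was not tested. LPA19, an assembly factor of photosystem II, had a log2 difference of -0.79 ± 0.09 (SE, limma adjusted p = 1.16e-05). As deposited it was smaller, at -0.33, and still called (limma adjusted p = 0.0119). SRX, a sulfiredoxin, stood at -0.36, and was called, but it turned to 0.11 as deposited and was not called with the pairs averaged (limma adjusted p = 0.123). NTRC and PSB27 were not called, at -0.10 and -0.33. As deposited NTRC was called higher, at 0.35 (limma adjusted p = 0.0450), and PSB27 stood at 0.03 and was not called.

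Some of the largest changes belong to probes that are unnamed here. Probe 3875 rose from 0.411 ± 0.110 to 5.64 ± 0.173 and probe 2188 from 1.18 ± 0.282 to 11.3 ± 1.73 (SD, n = 6 each). Probe 2911 fell from 9.86 ± 0.503 to 0.869 ± 0.0673 and probe 2917 from 6.39 ± 0.411 to 0.729 ± 0.0359 (SD, n = 6 each). All 4 were also called with the pairs averaged. In each of the 6 dark samples 2 unnamed probes stood at 100, and in light they averaged 24.0 ± 2.92 and 53.5 ± 7.53 (SD, n = 6 each). If 100 is a limit of the reading, their dark values are lower bounds. Both probes stood at this same value in all 6 dark samples, although they differed from each other in light. Scaling each column to its highest probe would not by itself tie 2 probes. The tie thus argues against such scaling as the only cause of the value 100. What set the value was not tested.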
